A study of Homo sapiens with 2 samples.

How the data were processed

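Total RNA of LN229 cells was measured on 2 Affymetrix arrays, per the labels: 1 from cells carrying a plasmid that drives miR-127-3p and 1 from cells carrying the plasmid alone. Biotin-labelled cRNA was prepared from Trizol-extracted RNA with an Affymetrix 3′ labelling kit, per the labels' protocols, and signals of such kits come mainly from transcript 3′ ends. The groups were taken from the genotype labels. The deposited values are probe set signal intensities on a linear scale, with no value missing or negative. Both deposited arrays lie on a common scale, judged from the values alone: after trimming 2% of probe sets at each end, the mean signal intensity was 500.1 on each. The software that summarised probes into probe sets and any background correction are not given in the sources used here, and no detection calls were used. No other column of per-sample values was present.

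The platform annotation table paired 41091 of 54613 non-control probe sets with 1 gene symbol and 1801 with several, and 11721 were unnamed here. Symbols were checked through Entrez gene identifiers against a RefSeq gene table of assembly GRCh38.p14, which matched 99.9% of them. Probe sets with several symbols or none were left out of gene counts, and 62 control probe sets were kept apart. Signals were turned into log2(signal + 1). A probe set entered if its mean log2 value over both arrays was above the median of all non-control probe sets, which is a signal of about 83.0. The entering probe set with the highest mean stood for its gene, giving 11985 genes of 19775 named. Counts and single gene values refer to that probe set, and other probe sets of a gene can differ from it. The log2 ratio was miR-127-3p minus control with the median over genes, 0.01, subtracted, and a fold is 2 to the power of that ratio, which understates the change of low genes because of the pseudocount of 1. Where a gene was below its array's median signal on the dimmer array, the fold is given as a lower limit against that median. This floor is a choice of this work and not a detection call. A filter on the mean leaves out some genes that are bright on 1 array and near 0 on the other.

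No test between groups was possible with 1 array each. Genes past 2-fold were counted by that fixed rule of size. The agreement of probe sets of a gene was used as a measure of error within the arrays. For 39 gene lists, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn with replacement from 10 bins of mean log2 value, and a list was called apart below percentile 2.5 or above 97.5. Lists with fewer than 5 entering genes got values only. The value of 1 cytoskeletal gene is not reported here. The lists covered named miR-127-3p targets, the DLK1-DIO3 cluster, microRNA machinery, septins, matrix, adhesion, migration, cell cycle, p53 targets, apoptosis, stress, metabolism, signalling, lineage markers, other cell types, ribosomal proteins, oxidative phosphorylation, histones and reference genes. Named genes were the 15 highest and 15 lowest ratios among genes whose probe sets agreed in sign, up to 2 members per direction of each list, all measured members of the first 2 lists, and GAPDH and ACTB. A gene with only 1 entering probe set met the rule of agreement without any comparison. KRT5, KRT18, ESRP1, S100A4, CLDN1, OCLN, SEPTIN9, SQLE, EBP, SREBF2, HSPH1, STAT3 and the genes of the last part of the closing section were chosen after their values were seen. Lists, rules and all settings but the last 3 given next were fixed before the data were examined.

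The alternatives were a 1.5-fold or 3-fold threshold, no filter or one at the 75th percentile, and values as deposited, quantile normalization, a loess trend (span 0.3) or each array's 75th percentile in place of median centring. Further ones were pseudocounts of 16 and 32, the mean of all entering probe sets, and only probe sets without a cross-match suffix. The last 3, added after the data were seen, were a floor at each array's median, only genes above the median on both arrays, and a signal above the 75th percentile on at least 1 array. A gene's value counted as moved when it shifted by more than the probe set spread of 0.41. A comparison of genes with miR-127-3p seed sites in 3′ UTRs was not run because no transcript sequence was used here. The procedure was tested on simulated arrays with the measured probe set spread as independent noise, and 11968 genes passed the filter. Of 50 genes made 4-fold higher all were counted as past 2-fold, as were 97.4% of 39 made 4-fold lower. Of genes made exactly 2-fold higher 36.0% were counted and of those made 2-fold lower 38.3%, and of 11782 unchanged genes 1.2%. Of random lists 3.5% were called apart. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used, and figures were drawn with matplotlib 3.10.9.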

Results

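Transcript levels were measured on Affymetrix expression arrays in cultures labelled as LN229, an established human glioblastoma line. Whether both cultures held the same line was not tested. One culture carried a pSUPER.neo plasmid driving the microRNA miR-127-3p and the other carried the plasmid without it. The question was which transcripts this microRNA regulates in a glioblastoma line. There was 1 array per group, so no difference below has a replicate check and no p-value is given. Signals of 54675 probe sets were used, and the median signal was 83.3 arbitrary units on the miR-127-3p array and 93.9 on the control array. The number of arrays, not a read depth, limits the precision. Log2 ratios of probe sets of the same gene had a spread of 0.41 per probe set (SD, from 5974 pairs), which holds no variation between cultures.

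Comparison of the miR-127-3p array with the control array asked which genes differed when the microRNA was overexpressed. Epithelial genes were among the lowest with miR-127-3p. KRT19, a keratin of simple epithelia, gave a signal of 5.64 with miR-127-3p and 12674 in the control, and EPCAM, an epithelial adhesion molecule, gave 30.2 and 9181. In the opposite direction UCA1, a long non-coding RNA, gave 8702 with miR-127-3p and 64.2 in the control, and RORB, a nuclear receptor, gave 3449 and 30.1. Of 11985 genes above the signal filter, 607 were at least 2-fold higher and 1039 at least 2-fold lower with miR-127-3p, which together is 13.7% of the genes. At least 8-fold differences were counted for 44 genes higher and 169 lower. Of 609 genes past 2-fold that had more than 1 probe set above the filter, 546 had all probe sets on the same side of 0. Pearson's correlation of log2 signals across all 11985 genes was 0.88, and genes are not independent replicates.

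**Figure D1:**
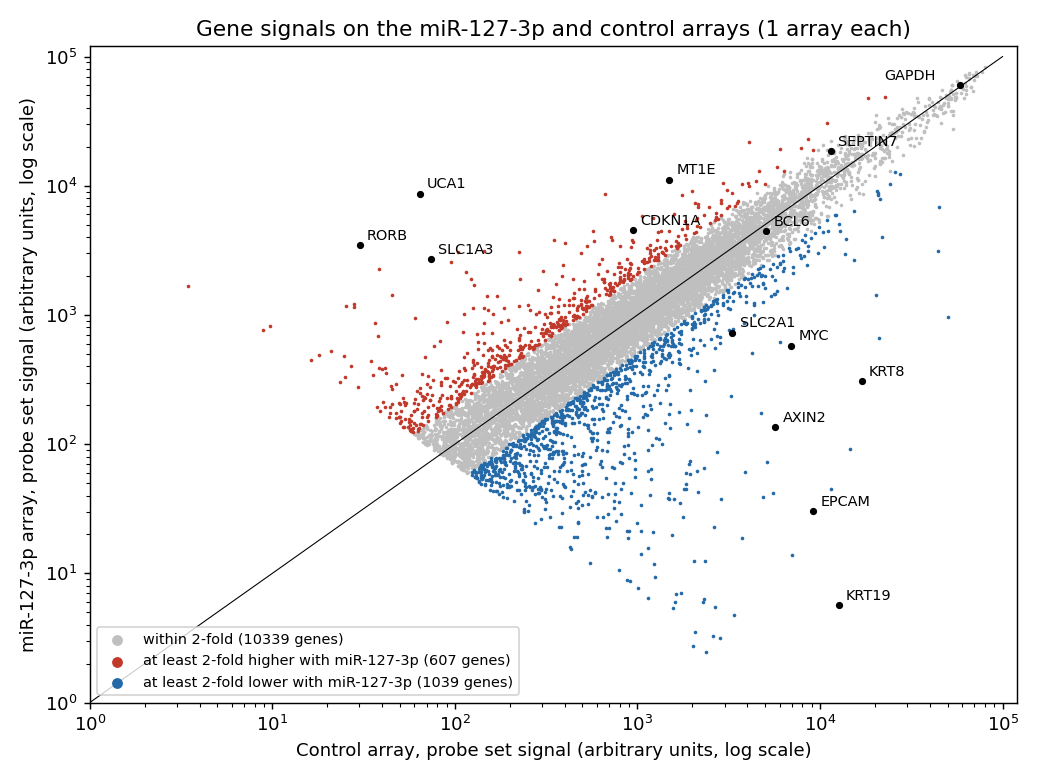
Signals of 11985 genes on the control array (x axis) and the miR-127-3p array (y axis), both in arbitrary units on log scales, 1 point per gene; the line marks equal signals and colours mark 2-fold differences. The 607 higher and 1039 lower genes flank a dense diagonal on which GAPDH, BCL6 and SEPTIN7 lie, while KRT19 and EPCAM lie far below it and UCA1 and RORB far above.

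Control probe sets gave the quality of RNA and labelling on each array. The ratio of the 3′ to the 5′ probe set was 0.97 with miR-127-3p and 0.98 in the control for GAPDH, and 2.95 and 3.36 for ACTB. Hybridisation spikes had a median log2 ratio of 0.14 over 9 probe sets, and poly-A spikes had one of -0.07 over 12 probe sets. The 3′ control probe set for 18S ribosomal RNA gave 29757 with miR-127-3p and 19414 in the control. GAPDH and ACTB themselves had log2 ratios of 0.02 and 0.05.

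Genes named in earlier work as targets of miR-127-3p were not apart from random lists as a group. At the brightest probe set, none of the 9 members above the filter reached a 2-fold difference in either direction, but other probe sets of 4 members did. SEPTIN7, a cytoskeletal septin, gave 18429 with miR-127-3p and 11511 in the control, a log2 ratio of 0.67, and its 3 probe sets ranged from 0.13 to 0.67. BCL6, a transcriptional repressor, had a log2 ratio of -0.21 with 3 probe sets between -1.28 and -0.21. XBP1, a factor of the unfolded protein response, was at -0.64. ITGA6, an integrin subunit, was at -0.61 and at -1.38 at its other probe set. PRDM1 was at 0.84, KIF3B at 0.49 and COA1 at 0.30, while SKI was at -0.09 and KMT5A at -0.01. Probe sets lay on both sides of 0 for SKI, from -1.44 to 0.21, for COA1, from -0.09 to 1.09, and for KMT5A, from -0.80 to 0.03. MMP13, a collagenase, was below the filter with signals of 16.5 and 2.25. The list median was -0.01, at percentile 37.5 among 10000 random lists of the same size matched on mean log2 signal. It was 0.06 with quantile normalization and 0.04 with the loess trend removed, and over all alternatives it ranged from -0.34 to 0.18. The lowest value, at percentile 3.80, came from the mean of all probe sets of each gene and the highest from no filter.

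Transcripts of the imprinted cluster that holds the miR-127 gene were below the filter. MEG3 gave signals of 35.7 with miR-127-3p and 53.8 in the control, MEG9 gave 52.8 and 65.8, DLK1 gave 7.81 and 49.2, and DIO3 gave 9.09 and 104. DIO3 alone of these 4 genes was above the array median, on the control array, and the arrays carry no measurement of the mature microRNA used here. The 14 measured genes of microRNA processing and silencing all stayed within 2-fold, with AGO2, the slicing Argonaute, at -0.59 and TNRC6B at -0.36, and DROSHA, the nuclear processing nuclease, at 0.51 and TNRC6C at 0.32. Their median of -0.0030 was at percentile 41.8. Of 8 septins above the filter 1 was at least 2-fold lower, SEPTIN6, which gave 78.5 with miR-127-3p and 395 in the control and was at least 4.74-fold lower. SEPTIN8 was at -0.61 and SEPTIN2 at 0.17. SEPTIN9 was at -0.48 and reached -1.41 at another probe set. The median of -0.28 was at percentile 6.85.

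Epithelial markers, fixed as a list of another cell type the cultures could hold, were lower with miR-127-3p, with a median log2 ratio of -6.53. Of 6 members above the filter, 5 were at least 2-fold lower and none was higher. With dim signals set to each array's median, KRT19 was at least 151-fold and EPCAM at least 110-fold lower, and ESRP1, a splicing regulator of epithelia, at least 13.6-fold. KRT8 was 55.4-fold lower, with a signal of 307 against 16926. The list median lay below those of all 10000 random lists, and with the same floor it was -4.78. Counting members below the filter too, 11 of 12 markers were brighter on the control array, and KRT5 alone was brighter on the miR-127-3p array. This difference runs along the same pair of arrays as every comparison that follows.

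The 15 genes with the lowest ratios were TESC, STK26, PLIN2, INHBB, CCEPR, DSP, CLRN3, MEST, FGF3, GAL, GPX2, SERPINF1 and RASSF6, besides KRT19 and EPCAM. Every one of them was below the array median on the miR-127-3p array, so only lower limits of the difference are given and the order within the group has no meaning. Their place among the 15 rests on these dim signals too. Each had only 1 probe set above the filter, so agreement of probe sets was not assessed for them. GPX2, a glutathione peroxidase of the gut epithelium, was at least 138-fold lower. DSP, which encodes the desmosomal protein desmoplakin, was at least 83.6-fold lower, with 13.8 against 6991. INHBB, an activin subunit, was at least 40.3-fold lower, STK26, a kinase, at least 33.8-fold, MEST at least 31.8-fold and PLIN2, a lipid droplet protein, at least 31.1-fold. TESC was at least 28.5-fold lower, GAL, which encodes the neuropeptide galanin, at least 27.6-fold, and the growth factor gene FGF3 at least 27.4-fold.

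The 15 genes with the highest ratios were SFMBT2, UCA1, RORB, CLEC7A, LINC01477, HSD17B2, CLEC2B, SERPINB7, PTPRR, SLC1A3, NLRP5, SCG5, CRH, RIMS2 and LYPD6B. Every one of them except SCG5 and CRH was below the array median on the control array, so the others have lower limits only and their order has no meaning. Their place among the 15 rests on these dim signals too, RIMS2 being at least 4.73-fold higher. Only RORB, PTPRR and CRH had more than 1 probe set above the filter. UCA1 was at least 91.0-fold higher with miR-127-3p, and RORB was at least 36.1-fold higher with all 3 probe sets on that side. SCG5, a secretory granule protein, was 29.2-fold higher, with 3096 against 104. CRH, which encodes corticotropin-releasing hormone, was 26.5-fold higher against a control signal of 94.7, close to the array median, and a second probe set gave 283 against 79.4. SLC1A3, a glial glutamate transporter, was at least 28.1-fold higher, and HSD17B2, a steroid dehydrogenase, at least 23.8-fold. SFMBT2, a Polycomb group gene, was at least 17.5-fold higher and NLRP5 at least 15.1-fold.

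Genes of adhesion, matrix and migration differed in both directions. Of 27 extracellular matrix genes, 5 were at least 2-fold higher and 2 lower, with THBS1, thrombospondin, 3.57-fold higher and COL11A1, a fibrillar collagen, 2.35-fold lower. POSTN, periostin, gave 211 against 40.2 and was at least 2.21-fold higher, and COL1A1 had a log2 ratio of -1.95 at its chosen probe set and -0.04 at another. The median of -0.09 was at percentile 10.5. Of 18 metalloproteinases and related genes, MMP3, stromelysin, was at least 5.48-fold higher, and TIMP3, an inhibitor of metalloproteinases, was 2.68-fold lower with 4 probe sets between -1.59 and -1.22. MMP14 was at 0.64, with 4 probe sets between 0.64 and 1.84. MMP15 was at least 2.11-fold lower, and the median of -0.12 was at percentile 21.4. Of 24 integrin and focal adhesion genes, 3 were at least 2-fold higher and 3 lower. ITGA3 and ITGA2 had log2 ratios of 1.28 and 1.14, ITGB3 was at -1.30 and ITGA7 was at least 9.97-fold lower. A second probe set of ITGA2 was at 0.38. The median of 0.01 was at percentile 45.8. Of 23 cytoskeletal regulators 22 stayed within 2-fold, with ROCK2 at -0.98, LIMK1 at 0.73 and MYH9 at 0.50. Their median of 0.22 was at percentile 93.0.

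Of 19 epithelial-mesenchymal markers, 6 were at least 2-fold lower and 2 higher. The higher genes were CDH11, a mesenchymal cadherin, with a log2 ratio of 2.38 and ACTA2, smooth muscle actin, with 1.38. The 3 probe sets of CDH11 ranged from 0.84 to 2.38. S100A4, a calcium-binding protein counted among mesenchymal markers, gave 3101 with miR-127-3p and 44196 in the control, a log2 ratio of -3.84. The median of -0.29 was at percentile 0.94, but it was 0.29 with only probe sets lacking a cross-match suffix, 1 of 3 alternatives of 13 under which the call was lost. EPCAM, KRT8 and KRT18 also belong to the epithelial list. Without these 3 genes the median of the other 16 was -0.03, at percentile 32.3. Among the 16, CLDN1, at least 25.6-fold lower, and OCLN, at -1.32, are epithelial markers too. In a split that was not among the fixed lists, the 12 mesenchymal members had a median of 0.16, at percentile 77.9.

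Of 17 p53 targets, genes that respond to DNA damage, 6 were at least 2-fold higher with miR-127-3p and none lower. CDKN1A, a cyclin-dependent kinase inhibitor, was 4.76-fold higher, with 4535 against 945. FAS, a death receptor, was 2.42-fold higher with 4 probe sets between 0.70 and 1.70, while GADD45A was at -0.77 and PHLDA3 at -0.46. The median of 0.56 was at percentile 99.97. Of 27 genes of DNA replication 3 were lower and none higher, with MCM2, a helicase subunit, at -1.25 and POLA1, a polymerase subunit, at -1.14, and with CCND1 at 0.52 and CDK4 at 0.48. Their median of -0.23 was at percentile 1.71, and this list was no longer apart from random lists under 3 of 13 alternatives. Of 28 mitotic genes 3 were lower, with CDK1, the mitotic kinase, at -1.48 and AURKB at -1.07. KIF20A was at 0.86 and NUSAP1 at 0.71, and the median of -0.0040 was at percentile 35.0. Of 17 apoptosis regulators BAD and BAX, both death-promoting, were at 1.16 and 1.13, though the probe sets of BAD lay on both sides of 0. BCL2, which is protective, was at -0.85 and BIRC2 at -0.64. The median of 0.13 was at percentile 77.6.

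Metallothioneins, which bind zinc and copper, were higher with miR-127-3p as a group, 6 of 7 by at least 2-fold. MT1E was 7.40-fold higher, with 11113 against 1490, and MT1H 5.36-fold, with 21923 against 4060. The median of 1.47 lay above those of all 10000 random lists. These genes are near-identical in sequence and the probe sets of all 6 members past 2-fold carry a cross-match suffix, so the share of each member is uncertain. Hypoxia and glycolysis genes were lower, 10 of 21 by at least 2-fold and none higher by that much. SLC2A1, the main glucose transporter, was 4.57-fold lower with 729 against 3310, and PDK1, which restrains pyruvate oxidation, was 3.92-fold lower with 3 probe sets between -1.97 and -1.03. ADM was at 0.62 and PFKFB3 at 0.25. The median of -0.70 lay below those of all 10000 random lists. The epithelial list differed by -6.53 on the same arrays, or by -4.78 with dim signals set to each array's median.

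Other metabolic and stress lists differed less. Of 14 cholesterol synthesis genes only DHCR7, a late enzyme of the pathway, passed 2-fold at its chosen probe set, at -1.05. INSIG1 was at -0.88, STARD4 at 0.45 and LSS at 0.25. At other probe sets SQLE reached -2.07, EBP -1.35, SREBF2 -1.19 and LSS 1.71. Their median of -0.44 was at percentile 0.60. Of 20 amino acid response genes 6 were lower, among them VLDLR at -1.92 and CTH, an enzyme of cysteine synthesis, at -1.50, and 1 was higher, ATF5 at 1.42. A second probe set of CTH was at -0.46. The median of -0.31 was at percentile 0.81, a call lost under 2 of 13 alternatives. Of 20 unfolded protein response genes only CHAC1 passed 2-fold at its chosen probe set, and against the array median it was at least 1.56-fold lower. PPP1R15A was at 0.75 and ERN1 at 0.67, but at other probe sets they reached 1.45 and 1.36. The median of -0.04 lay inside the central 95% of random lists. None of 11 heat shock genes passed 2-fold at its chosen probe set, HSPB1 being at 0.96 and HSPA4L at -0.73. HSPH1 reached 1.71 at another probe set, and the median of -0.14 was at percentile 14.3. All 19 oxidative phosphorylation genes stayed within 2-fold and 18 had ratios above 0, with CYCS, cytochrome c, at 0.64 and SDHD at -0.62. Their median of 0.26 was at percentile 95.8. All 16 ribosomal protein genes stayed within 2-fold and 15 had ratios below 0, with RPL3 at -0.49 and RPLP1 at 0.20. Their median of -0.20 was at percentile 2.15, a call lost under 4 of 13 alternatives.

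Wnt pathway genes were lower with miR-127-3p for 7 of 18 members and higher for 2. NKD1, a feedback inhibitor of the pathway, was at least 46.4-fold lower, with all 3 probe sets brighter in the control. AXIN2, another feedback inhibitor, was 42.2-fold lower with 135 against 5688. DKK1, a secreted inhibitor, was 2.93-fold higher and WNT5A, a ligand, 2.26-fold higher. The median of -0.58 was at percentile 0.01. Of 11 Notch pathway genes 4 were lower and none higher. JAG2, a ligand, was at least 5.97-fold lower and NRARP at least 2.94-fold, while NOTCH2 was at 0.19. The median of -0.91 was at percentile 0.07. Of 19 immediate early genes 5 were lower and 4 higher. MYC, a growth-promoting transcription factor, was 12.1-fold lower with 578 against 6931, and IER3 was at -1.30. KLF4 was at 1.59 and DUSP4, a MAP kinase phosphatase, at 1.41, and the median of -0.18 lay inside the central 95% of random lists. The epithelial list, at -6.53 or at -4.78 with dim signals set to each array's median, differed on the same arrays as these Wnt and Notch genes.

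Of 23 interferon response genes 4 were at least 2-fold higher and none lower. TRIM22, an antiviral protein, gave 3788 with miR-127-3p and 938 in the control, and XAF1 was 2.94-fold higher, while IFITM1 was at -0.76 and OAS1 at -0.34. The median of 0.41 was at percentile 99.7. Of 12 YAP targets 4 were higher and none lower. NT5E, the ectonucleotidase CD73, was 6.12-fold higher and CCN1, a matrix-associated signalling protein, 2.93-fold, with TEAD4 at -0.64 and F3 at -0.51. The 4 probe sets of NT5E ranged from 0.76 to 2.61. The median of 0.52 was at percentile 99.9. Of 18 NF-kB and cytokine genes CCL20, a chemokine, was at least 14.7-fold lower and CXCL8, interleukin-8, 2.63-fold lower. IL11 was 3.08-fold higher and RELB was at 0.62. The median of -0.42 was at percentile 1.59, a call lost under 5 of 13 alternatives. Of 18 TGF-beta genes BAMBI, a decoy receptor, was 4.67-fold lower and SMAD6, an inhibitory SMAD, 2.88-fold lower. TGFBR1, a receptor, was 2.70-fold higher and TGFB2 was at 0.91. The median of -0.23 was at percentile 2.64. Of 19 receptor tyrosine kinase and PI3K genes 2 were higher, EGFR at 1.99 and IRS1, an insulin receptor substrate, at 1.43. The 5 probe sets of EGFR ranged from 0.01 to 1.99. IGF1R was at -0.76 and ERBB3 at -0.73, and the median of 0.08 was at percentile 69.1.

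Of the lineage lists, those of glioma stem and mesenchymal glioblastoma markers lay outside their random ranges. Of 11 glioma stem and neural progenitor markers 6 were at least 2-fold lower with miR-127-3p and none higher. FUT4, the enzyme that makes the CD15 antigen, was 10.0-fold lower with 83.7 against 842, and SOX9 was 3.11-fold lower with both probe sets near -1.6. OLIG2 was at 0.05. The median of -1.03 was at percentile 0.01. Of 13 mesenchymal glioblastoma markers 10 had ratios above 0 but none of these reached 2-fold at its chosen probe set, with FOSL2 at 0.92 and CASP1 at 0.84. At other probe sets CASP1 reached 1.68 and STAT3 1.14. BHLHE40 was 2.75-fold lower, with a second probe set at -0.31. LGALS3 was at -0.07, and the median of 0.46 was at percentile 99.6. It was 0.22 with the filter at the 75th percentile, the 1 of 13 alternatives under which this call was lost. Of 6 astrocyte markers SLC1A3 was higher and ALDOC, at -1.33, lower, with S100B at -0.37 and a median of -0.19 at percentile 21.5. Of 5 oligodendrocyte lineage markers SOX10 was 3.14-fold and CSPG4 2.51-fold lower, and the median of -0.58 was at percentile 5.44. Of 5 neuron markers SNAP25 was at 1.18 and MAP2 at 0.73, SYT1 at -1.33, and GAP43 was at least 1.57-fold lower, with a median of 0.43 at percentile 94.0. Among 6 endothelial and pericyte markers ACTA2 was at 1.38, ENG at 1.21, CSPG4 at -1.33 and RGS5 at -0.55, with a median of 0.23 at percentile 83.1. Only 2 of 9 microglia and blood markers passed the filter, CD14, at least 1.26-fold lower, and HBB at -0.36. Of 7 histone genes H2BC21 was 3.20-fold higher and H1-2 was at -0.89, with a median of 0.03 at percentile 56.0. All 13 reference genes stayed within 2-fold, from PGK1 at -0.70 and HPRT1 at -0.54 to SDHA at 0.45, with a median of 0.02 at percentile 37.5. The lowest of the 6 probe sets of PGK1 was at -1.08.

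**Figure D2:**
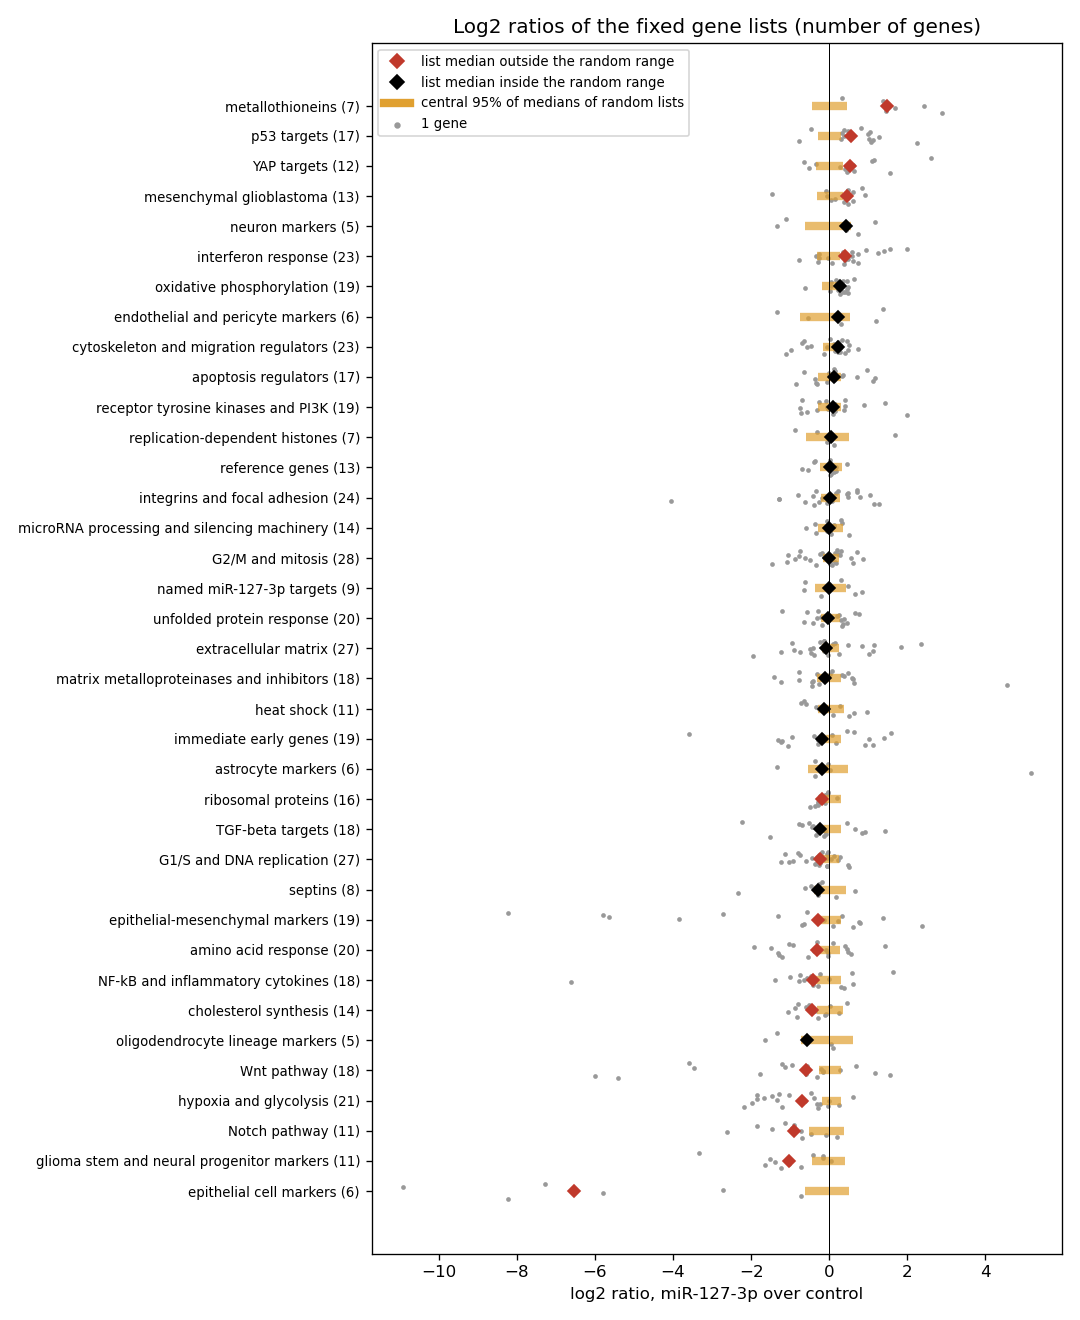
Log2 ratios of miR-127-3p over control (x axis) for the 37 gene lists with at least 5 genes above the filter (y axis, number of genes in brackets); grey points are genes, diamonds list medians and bars the central 95% of medians of random matched lists. Metallothioneins lie furthest right at 1.47 and epithelial cell markers furthest left at -6.53, and red diamonds mark the 16 lists outside their random range.

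Of the 37 lists compared with random lists, 11 lay below and 5 above the central 95%, where chance would place 1.85. That number holds for genes that vary independently, whereas genes of the same chromosome tended to differ in the same direction. These lists share members, and the percentiles describe this pair of arrays and not the spread between cultures. Median and mean differed in sign for the lists of named targets, metalloproteinases, extracellular matrix, integrins, astrocytes, neurons and reference genes. The median turned its sign under another scaling for named targets, microRNA machinery, integrins, mitosis, unfolded protein response and histones. For microRNA machinery, mitosis and unfolded protein response it did so only under scalings that shift all genes alike, which leave the percentile as it is. Probe sets lay on both sides of 0 for TNRC6B, SEPTIN2, TEAD4, PHLDA3, LSS, OAS1, NOTCH2 and GAPDH.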

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

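Probe sets that the annotation does not pair with a single gene lie outside the gene counts, and 253 of 4847 such probe sets above the filter were at least 2-fold higher on the miR-127-3p array, while 376 were at least 2-fold lower. They were picked out because a signal above that of the control array stood in data the comparison did not use. Of the 11985 genes, 607 were higher and 1039 lower by the same rule. These shares are similar, so the probe sets did not stand out from the genes.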

How the results depend on the processing

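No paired analysis was possible because each group had 1 array, and leaving out an array would leave no comparison. The comparison of genes with miR-127-3p seed sites, with its alternatives, was not run because no transcript sequence was used here. Counts of genes past 2-fold depended most on the filter and the threshold. Without a filter 2531 genes were higher and 3400 lower, 1327 past 2-fold had agreeing probe sets, and the probe set spread was 1.11. With the filter at the 75th percentile these were 259, 387 and 166, with a spread of 0.26. A 1.5-fold threshold gave 1743 higher, 2167 lower and 1359 agreeing, and a 3-fold threshold 188, 472 and 201. Without cross-match probe sets 267 genes agreed and 10 lists were apart in place of 16. With a signal above the 75th percentile on at least 1 array, an alternative added after the data were seen, the counts were 361 higher, 648 lower and 277 agreeing, since fewer genes (8457) entered. Under the other scalings, pseudocounts, probe set rules and floors the counts stayed within 1.5 times of the main ones, and lower genes made up 54.9% to 64.5% of genes past 2-fold against 63.1%. Of 466 list medians recomputed over 13 settings, 18 lost their call, 4 gained one and none was called on the opposite side, though some medians crossed 0 without a call. The lost calls were in the lists of DNA replication, NF-kB, amino acid response, epithelial-mesenchymal, mesenchymal glioblastoma and ribosomal protein genes, and the cause was not tested. Of 2030 values of 170 named genes, 112 moved by more than the probe set spread and none past 2-fold changed sign. Signals under the array medians of 83.3 and 93.9 set lower limits only.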

Other observations

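Tests in this part were chosen after the results were seen, except the loess setting for the hypoxia list. For the centring of each chromosome, the outcome to look for was written down before the centring was run. The hypoxia pattern had been seen by then. The genes of this paragraph were picked after their values were seen, and no group was tested. Among genes for plasma proteins, SERPINA3 gave 973 with miR-127-3p and 49979 in the control, TF, transferrin, gave 663 and 20948, A2M gave 1424 and 20234, SERPINA1 gave 65.2 and 2324, and SERPINA5 gave 512 and 4250. Among genes known from intestinal crypts and Wnt signalling, ASCL2 gave 40.1 and 1178, LGR5 gave 7.32 and 327, NOTUM gave 64.5 and 969, SP5 gave 121 and 887, LGR6 gave 39.2 and 563 and PROX1 gave 167 and 2387. VIL1, the villin of brush borders, gave 45.4 and 1847 with all 4 probe sets brighter in the control, and TFF3 gave 72.3 and 807. CDX1, CDX2, KRT20, CDH17, CEACAM5, LGALS4 and MUC2, also known from the intestine, gave between 3.85 and 78.7 on both arrays at their brightest probe sets. Some secretory and neuronal genes differed in the opposite direction, while the fixed neuron list was not apart from random lists. BEX1 gave 8660 against 668, DLX1 gave 8506 against 1756, DLX2 gave 3649 against 946, SCG2 gave 3595 against 399, BDNF gave 1720 against 128 and RELN gave 481 against 24.7.

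CDKN2A, a tumour suppressor gene commonly described as deleted in LN229, gave 37.9 with miR-127-3p and 1587 in the control, and all 3 of its probe sets were brighter on the control array. A candidate explanation for this and for the epithelial markers is a minor share of epithelial cells in the control culture, or a different cell line there. A minor share would dilute the other cells only slightly, so it alone would not give the 44 genes at least 8-fold higher with miR-127-3p. Some of these rest on dim control signals, but against the floor UCA1 was still at least 91.0-fold and RORB at least 36.1-fold higher. No test here bears on either for these markers, and typing of short tandem repeats, which would bear on the identity of the cells, was not used here. Noise of dim signals is argued against by the median of -4.78 that remained with a floor at the array medians. Silencing of the 6 epithelial genes by miR-127-3p was not tested. No 3′ UTR sequence was used here, and a search for seed sites alone could neither show nor exclude it. For the epithelial markers a minor share of other cells, a larger replacement of the cells and a different line stay open. So do a subclone and an effect of the microRNA. If CDKN2A is deleted in LN229 as described, neither an effect of the microRNA nor a subclone of LN229 would account for its control signal. That deletion was not checked here.

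Genes of the same chromosome tended to differ in the same direction. Of 22 autosomes, 17 had a median log2 ratio outside the central 95% of random matched gene lists, where chance gives 1.1, and 16 and 18 did with the loess trend removed and with the 75th percentile filter. Chromosome 10 was lowest, with a median of -0.40 over 453 genes, 75.3% of them below 0, and a median of -0.32 among genes within 2-fold. Chromosome 9 was highest, at 0.27 over 487 genes, with chromosome 15 at 0.21 and chromosome 7 at 0.20. Chromosomes 12, 14 and 21 stayed inside their random ranges in all 3 settings, and 13 and 17 did except with the 75th percentile filter. Chromosome 16 was no longer outside its range with the loess trend removed, nor was chromosome 19 with the 75th percentile filter. Neither copy number nor a trend with base composition was tested, so these medians leave open whether the 2 cultures had different genomes.

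The hypoxia and glycolysis list, at -0.70, was weighed against a trend of the ratio with signal and against lost copies of chromosomes. With the loess trend removed its median was -0.72. The random lists were already matched on mean log2 signal, and the trend was too small for its removal to take away -0.70. That size argues against the trend as the whole cause. With each chromosome centred on its own median it was -0.61. The autosome medians, from -0.40 to 0.27, were too small for this centring to remove -0.70. Their size argues against shifts of whole chromosomes as the whole cause, while losses of parts of chromosomes were not tested. Oxygen, density and medium of the cultures, other cells in the control culture and the microRNA itself stay open as possible explanations and were not tested.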
